A study of Mus musculus with 15 samples.

How the data were processed

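Open chromatin was profiled by ATAC-seq, in which a transposase cuts accessible DNA, in microglia sorted by flow cytometry from mouse brain. The 15 libraries fell into 7 groups by genotype, age and methoxy-X04 labelling, with 3 libraries for IRF8KO at P9 and 2 for every other group. Per the labels' protocols, cells were isolated without enzymes, nuclei were tagmented with the Nextera kit, and libraries were amplified by PCR and size-selected. Per the submitters' processing notes, Bowtie2, MACS2 2.2.7.1, deepTools and bcl2fastq were used with the mm10 build, and the notes give no order or settings. The deposited lists hold one library each, so the authors called peaks per sample and not on pooled samples. The column of fold enrichment at each summit is a ratio the authors deposited, and the 2 columns of −log10 p and −log10 q were also deposited by the authors as their peak caller gave them. The last column, the distance from a peak's start to its summit, was deposited by the authors in base pairs. The lists held 126070 to 194399 summits per library. Read counts and depths were not analysed here, so no counting interval is given, and the strength of a library was described by the −log10 p of its peak at rank 30000, which ran from 6.04 to 80.65.

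Peaks were ranked by −log10 p within a list, since the authors' fold and p describe a peak only within its own list. Regions were the summits of the 30000 top peaks of the 15 libraries on chromosomes 1 to 19 and X, taken in order of rank and dropped within 400 bp of an accepted region, which left 65409 regions. A region was strong in a library when one of the 30000 top peaks had its summit within 200 bp. It was absent when none of the 126070 top peaks, the length of the shortest list, had a summit within 400 bp. A region was higher in one group than in another when it was strong in every library of the first and absent in every library of the second, and lower in the reverse case. For the genotype effect over both ages, presence as a strong region was also tested by a two-sided exact permutation test within age, with 60 arrangements, and adjusted by the Benjamini-Hochberg method over the regions whose totals could reach the smallest p. Strong regions were summed over the genes of 21 lists and compared between genotypes by the same exact test, adjusted over lists. Called regions at the genes of a list were compared with 10000 random gene lists matched on eligible regions per gene, adjusted over lists and directions within a comparison. A region was eligible when it was strong in every library of at least 1 of the groups compared.

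Regions were assigned to the nearest protein-coding gene body within 100 kb, using the RefSeq genes of GRCm38.p6, the assembly that mm10 names. The gene table gives no strand or exons, so the planned distance to the transcription start was replaced by the distance to the gene body, and exons, introns and promoters were not told apart. Of the regions, 91.3% had a gene, and 19.5% lay within 1 kb of a gene end against 5.0% after a shift of 50 kb. No genome sequence was used here, and the planned motif comparison was not run. Named genes followed a rule fixed beforehand. The rule took the genes of the 10 called regions with the best mean rank in each direction, then up to 15 genes of the lists with a called region, and Irf8. Genes of a list without a called region could be named with their counts. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. No 2 libraries held identical values. The sample numbers carried by the deposited lists, 4 and 5, occur in WT at P9 and in IRF8KO at P9 and at P14, so these 3 groups probably came from different sequencing runs; no run is given in the labels. None of 5 male-specific chromosome Y genes had a peak in any library.

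The rules were tested on simulated libraries made from the real ranks and their spread, with 10 rounds over 65409 regions and 200 regions removed in each. The rule recovered 99.0% of the removed regions for IRF8KO against WT at P9, 99.0% at P14, 99.1% for X04 negative 5xFAD against WT and 98.7% for X04 positive against X04 negative 5xFAD. Mean false calls were 0 in the former 3 designs and 21.2 in the last. Both groups were simulated around the same mean ranks with random noise alone. False calls from a weak library or a run difference could therefore not appear, and these counts do not bound them. Removed regions were drawn from the better ranked ones and put beyond every list, so their recovery was nearly assured. Regions moved down 4-fold in rank were recovered at 0.0%, 0.0%, 0.0% and 2.4%, so the rule finds losses and not weakening. The list test gave p under 0.05 for 1 of 100 random lists over 12190 genes and 0.0002 for a list with added calls. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives were the number of top peaks (20000 and 50000), absence judged in the full lists, peak intervals in place of summits with at least 1 bp of overlap, strong against not strong, assignment within 20 kb, and each library left out. Comparisons, lists, naming rule and these alternatives were fixed before the data were examined; regions taken without the X04 positive libraries and pairs of the same replicate number were added afterwards.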

Results

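Chromatin accessibility was compared in sorted microglia, the resident macrophages of the brain, from WT and IRF8KO mice at postnatal days 9 and 14 (P9 and P14) and from WT and 5xFAD mice at 10 months. IRF8 is a transcription factor of the myeloid lineage. The 5xFAD line carries human transgenes and forms amyloid plaques. Methoxy-X04 is a dye that binds amyloid, and 5xFAD microglia were sorted as X04 negative or X04 positive. The animals at 10 months, WT included, received this dye, and those at P14 did not. Each of the 7 groups had 2 libraries except IRF8KO at P9, which had 3. The −log10 p of the peak at rank 30000, the authors' value, was 77.47 ± 3.7 (SD, n = 3) in IRF8KO and 46.69 ± 10.78 (n = 2) in WT at P9, and 24.69 ± 2.63 (n = 2) in IRF8KO and 64.98 ± 4.53 (n = 2) in WT at P14. It was 20.87 ± 3.17 in WT, 22.1 ± 3.1 in X04 negative and 6.16 ± 0.18 in X04 positive microglia at 10 months (each n = 2).

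The strong regions of IRF8KO and WT libraries overlapped with a Jaccard index, shared regions over all regions of the pair, of 0.6 to 0.61 at P9 and 0.59 at P14, while libraries of WT at P9 and P14 overlapped at 0.79 to 0.82. IRF8KO replicates overlapped at 0.83 to 0.84 at P9 and at 0.75 at P14. The X04 positive replicates overlapped with each other at only 0.35, and X04 negative microglia overlapped with WT at 10 months at 0.74 to 0.76.

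**Figure D1:**
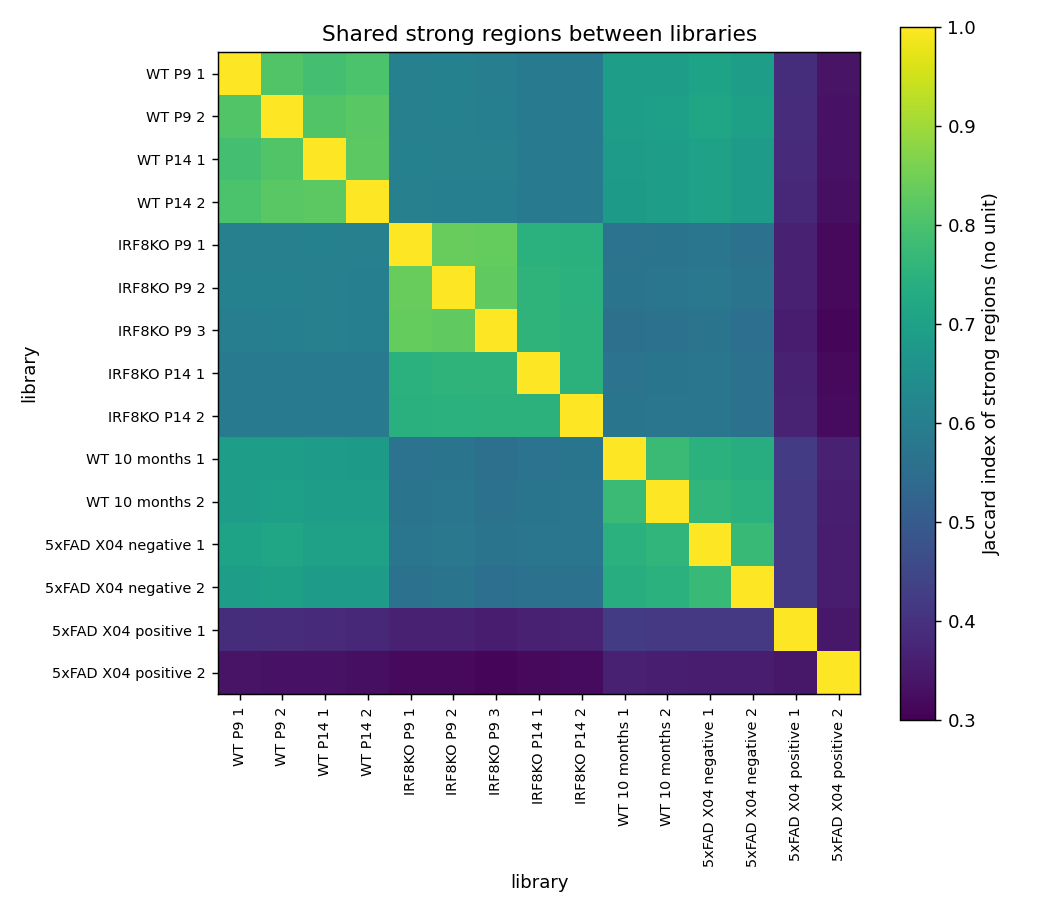
Jaccard index of strong regions (no unit, colour) for every pair of the 15 libraries, which are on both axes. IRF8KO and WT libraries at P9 share 0.6 to 0.61, and the X04 positive replicates share 0.35.

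The targeted gene was examined in every library. Irf8 lies on chromosome 8 from 120736358 to 120756694 (mm10), and the region from 120736055 to 120736455, centred 103 bp outside the gene, was strong in all 15 libraries. Strong regions at Irf8 numbered 11 ± 0.0 in WT and 9.67 ± 1.15 in IRF8KO at P9, 12 ± 0.0 and 10.0 ± 1.41 at P14, and 9.0 ± 0.0 in WT, 9.5 ± 0.71 in X04 negative and 5.0 ± 2.83 in X04 positive microglia at 10 months. No region assigned to Irf8 was called between IRF8KO and WT. Peaks outside a deleted part check nothing, and the deleted part is not given in the sources used here, so the genotype labels were not tested by this locus.

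IRF8KO microglia had no strong regions at Sall1, a transcription factor of microglial identity, and had more strong regions than WT at genes of border-associated macrophages, the macrophages of the brain surfaces. Sall1 had 4.5 ± 0.71 strong regions in WT at P9 and 5.0 ± 0.0 at P14 (each n = 2), and 0.0 ± 0.0 in IRF8KO at P9 (n = 3) and P14 (n = 2). F13a1, which encodes coagulation factor XIII A, had 1.0 ± 0.0 strong regions in WT and 4.0 ± 0.0 in IRF8KO at both ages. Cxcl1, a neutrophil-attracting chemokine, had 0.0 ± 0.0 in WT at both ages, against 4.33 ± 0.58 in IRF8KO at P9 and 5.0 ± 0.0 at P14. Over both ages 2494 regions rose and 2473 fell in IRF8KO by the exact permutation test within age (n = 5 and 4, p = 0.017, the smallest the design allows, adjusted p = 0.021), of 6326 regions that could reach that p. This test sets strong against not strong, so a region that fell may be weaker and not absent. Within each of the 21 lists the same numbers of regions passed when adjusted over the list alone. Since 78.5% of the testable regions share the smallest p, this was nearly assured and adds no support.

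By the rule of strong against absent, 516 regions were higher and 557 lower in IRF8KO at P9, and 587 were higher and 695 lower at P14. With 20000 top peaks these were 214, 278, 292 and 334, and with 50000 they were 1544, 1323, 1588 and 1890, so the balance turned at P9. With 30000 top peaks 304 regions were higher and 402 lower at both ages, and none were called in opposite directions. Among regions eligible at both ages, 86.3% of those lower at P9 were also lower at P14, where 9.9 shared regions would be expected of independent lists. The share for higher regions was 80.6%, with 5.6 expected. Of the P14 calls so eligible 68.1% and 73.6% were shared, and of all P9 calls, eligible at P14 or not, 72.2% and 58.9%. The one-sided Fisher's exact test across regions, which are not independent replicates, gave log10 p of −672.5 and −544.4. Groups of 3 and 2 libraries cannot reach an exact p below 0.1, and groups of 2 cannot reach one below 0.333, so no region was tested within an age. The sample numbers 4 and 5 occur in WT at P9 and in IRF8KO at P9 and at P14, so these groups probably came from different sequencing runs, which the labels do not give. Called regions lay within 1 kb of a gene end in 13.2% to 17.8% of cases, against 32.9% to 33.2% of eligible regions.

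The leading regions lower in IRF8KO lay 9.3 kb from Knstrn (chromosome 2, 118804511 to 118804911), inside P3h2 (chromosome 16, 26041306 to 26041706) and 7.1 kb from Rasgrf1 (chromosome 9, 90033926 to 90034326). Their mean ranks in WT were 503.5 ± 84.7, 725.2 ± 227.3 and 945.8 ± 390.8 (n = 4). The others of the leading 10 lay at Lrrc4c, Plppr4, Sult1c1, Mrap2, Lsm14a, Rasgrf2 and Enah. The leading regions higher in IRF8KO lay 14.3 kb from Sdr16c5 (chromosome 4, 3981404 to 3981804), 3.9 kb from Serpinb2 (chromosome 1, 107496806 to 107497206) and inside Dlgap1 (chromosome 17, 70570829 to 70571229). Their mean ranks in IRF8KO were 1067.0 ± 395.7, 1294.6 ± 1345.5 and 1880.2 ± 583.4 (n = 5). The others lay at Nt5e, Olfr985, Samsn1, Micu3, Vmn2r96, Gm9733 and Gm40011.

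At Sall1 4 regions fell by the exact test, among them one 90.4 kb from the gene at 89134411 to 89134811 and one inside it at 89043528 to 89043928 on chromosome 8, and 2 of the 4, the former included, were also lower at both ages by the rule of strong against absent. Of the 24 measured genes of microglial identity, 6 had regions that only fell, 3 had regions that only rose (Entpd1, P2ry12 and Sall3), and Bin1 had both. The genes with falling regions included Sall1, Slc2a5, Sparc, Selplg and Crybb1. Strong regions summed over this list numbered 114.0 ± 1.41 in WT and 101.33 ± 2.89 in IRF8KO at P9, and 118.5 ± 0.71 and 109.5 ± 3.54 at P14, a mean difference of −10.83 (exact permutation test within age, p = 0.0167, adjusted p = 0.044). That p is the smallest that 60 arrangements allow, and all 8 lists past this test had it. Their adjusted p depends on how many lists share that value, so it does not measure a single list. Every IRF8KO library lay below every WT library of its age, and the difference was −5.92 with 20000 and −19.17 with 50000 top peaks (exact adjusted p = 0.039 and 0.029). Cx3cr1, the fractalkine receptor of microglia, had 6.0 ± 0.0 strong regions in WT and 5.0 ± 0.0 in IRF8KO at both ages, with no region past the test. Tmem119, a marker of homeostatic microglia, had 2.0 ± 0.0 in all 4 groups.

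Of the 24 measured myeloid transcription factors, 5 had regions that only rose by the exact test (Cebpa, Id2, Mef2a, Nr4a1 and Zeb2), 4 had regions that only fell (Bach2, Maf, Mitf and Tfec) and 3 had both (Bach1, Bhlhe40 and Runx1), which made 11 rising and 12 falling regions. At Bach2 3 regions fell, at Maf 2, and at Runx1 3 fell and 1 rose. Of the 25 measured genes of complement and phagocytosis, 5 had regions that only rose (C3, Cd36, Fcgr2b, Itgb2 and Mertk), 7 had regions that only fell, among them Tlr7, a receptor for RNA, with 2, and Tlr2, a receptor for bacterial lipoprotein, had 2 that fell and 1 that rose. Of the 22 measured inflammatory genes, 6 had regions that only fell (Ccl12, Ccl2, Ccl3, Il12b, Il1b and Il6), 4 had regions that only rose (Ccl4, Cxcl1, Nfkbiz and Tnfaip3), and Nlrp3 had both, which made 11 rising and 8 falling regions. The difference of their summed strong regions was 3.17 (exact adjusted p = 0.044), was 6.08 with 20000 top peaks and 1.92 without WT replicate 2 at P14, and turned to −5.75 with 50000. At Batf3, a partner of IRF8 in dendritic cells from the IRF family list, 2 regions fell. The IRF family list differed by −5.58 (exact adjusted p = 0.044), and its sign turned with 20000 and with 50000 top peaks (0.67 and 1.58).

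Of the 14 measured genes of border-associated macrophages, 5 had regions that only rose (Cp, F13a1, Mrc1, Ms4a7 and Pf4), and Cd163, a haemoglobin scavenger receptor, had both. By the exact test over both ages these made 11 rising regions of 30 eligible, where random matched lists gave a mean of 2.69 (two-sided permutation p = 0.0008, adjusted p = 0.034). This was the only one of 21 lists past that test, and it did not pass with assignment within 20 kb (8 of 23 regions, permutation adjusted p = 0.15). The random lists were matched on eligible regions and not on strong regions in WT, and genes with few of the latter have more room to gain. Strong regions of the list numbered 19.5 ± 0.71 in WT and 30.0 ± 2.65 in IRF8KO at P9, and 21.0 ± 1.41 and 33.0 ± 1.41 at P14 (difference 11.25, exact adjusted p = 0.044). Ms4a7 had 1.0 ± 0.0 in WT and 3.0 ± 0.0 in IRF8KO at both ages. Lyve1 and Cbr2, other markers of these cells, had 1.0 ± 0.0 and 2.0 ± 0.0 in all 4 groups.

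Genes of cholesterol and lipid handling had more strong regions in IRF8KO, 79.67 ± 1.53 against 66.0 ± 1.41 at P9 and 75.0 ± 2.83 against 64.5 ± 3.54 at P14 (difference 12.08, exact adjusted p = 0.044). Of the 23 measured, 10 had regions that only rose, among them Lpl, a lipoprotein lipase, Plin2, a lipid droplet protein, and Apoe, and 3 had regions that only fell, among them Lpcat2 and Pparg. Lpl had 1.0 ± 0.0 strong regions in WT and 3.0 ± 0.0 in IRF8KO at both ages. TGF-beta signalling genes also had more (difference 9.75, exact adjusted p = 0.044), with 3 rising regions at Smad3, and this call was lost with 50000 top peaks (4.17, exact adjusted p = 0.075). Of the 18 measured, 6 only rose, Tgfbr2 only fell and Smad7 had both, which made 9 rising and 2 falling regions. The exact test on sums asks only whether libraries separate by genotype. Neither the lipid nor the TGF-beta list passed against random matched lists. Genes of disease-associated microglia differed by 8.17 and did not pass (exact adjusted p = 0.095), though they did with 20000 top peaks (4.25, exact adjusted p = 0.039), and with 50000 the difference was 2.08 (exact adjusted p = 0.442). Of the 30 measured, 6 had regions that only rose (Ank, Apoe, Ch25h, Clec7a, Gpnmb and Lpl) and 4 had regions that only fell (Cadm1, Ccl6, Cd52 and Spp1).

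Among markers of other cell types, the neuron and oligodendrocyte lists had fewer strong regions in IRF8KO, with differences of −7.33 and −7.42 (exact adjusted p = 0.044 for both). Of the 6 regions that fell at genes of the neuron list, 3 lay at Bcl11a, and 0 rose. With 20000 top peaks the neuron call was lost (−1.92, exact adjusted p = 0.105), and the oligodendrocyte difference was −4.25 (exact adjusted p = 0.039). Monocyte, neutrophil and lymphocyte genes differed by 2.17, 2.0 and 0.0 (exact adjusted p = 0.175, 0.175 and 1.0), and the former pair passed with 50000 top peaks (6.92 and 5.0, exact adjusted p = 0.029 for both). Astrocyte and endothelial genes differed by −1.42 and −2.92 (exact adjusted p = 0.175 and 0.095), and both passed with 50000 top peaks (−4.67 and −5.5, exact adjusted p = 0.029 for both). Interferon response genes differed by 0.83, lysosome genes by −1.0, antigen presentation by −2.83, complement and phagocytosis by −3.08, cell cycle by 2.75, myeloid transcription factors by 5.42 and immediate early genes by 11.58, none past the test (exact adjusted p = 0.387, 0.63, 0.206, 0.175, 0.175, 0.272 and 0.078). Immediate early genes passed with 20000 and with 50000 top peaks (10.75 and 3.75, exact adjusted p = 0.039 and 0.029), and lysosome genes with 20000 (−9.25, exact adjusted p = 0.039). With 50000 top peaks interferon response genes also passed (3.83, exact adjusted p = 0.029), and complement and phagocytosis passed with the sign turned (5.92, exact adjusted p = 0.029).

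**Figure D2:**
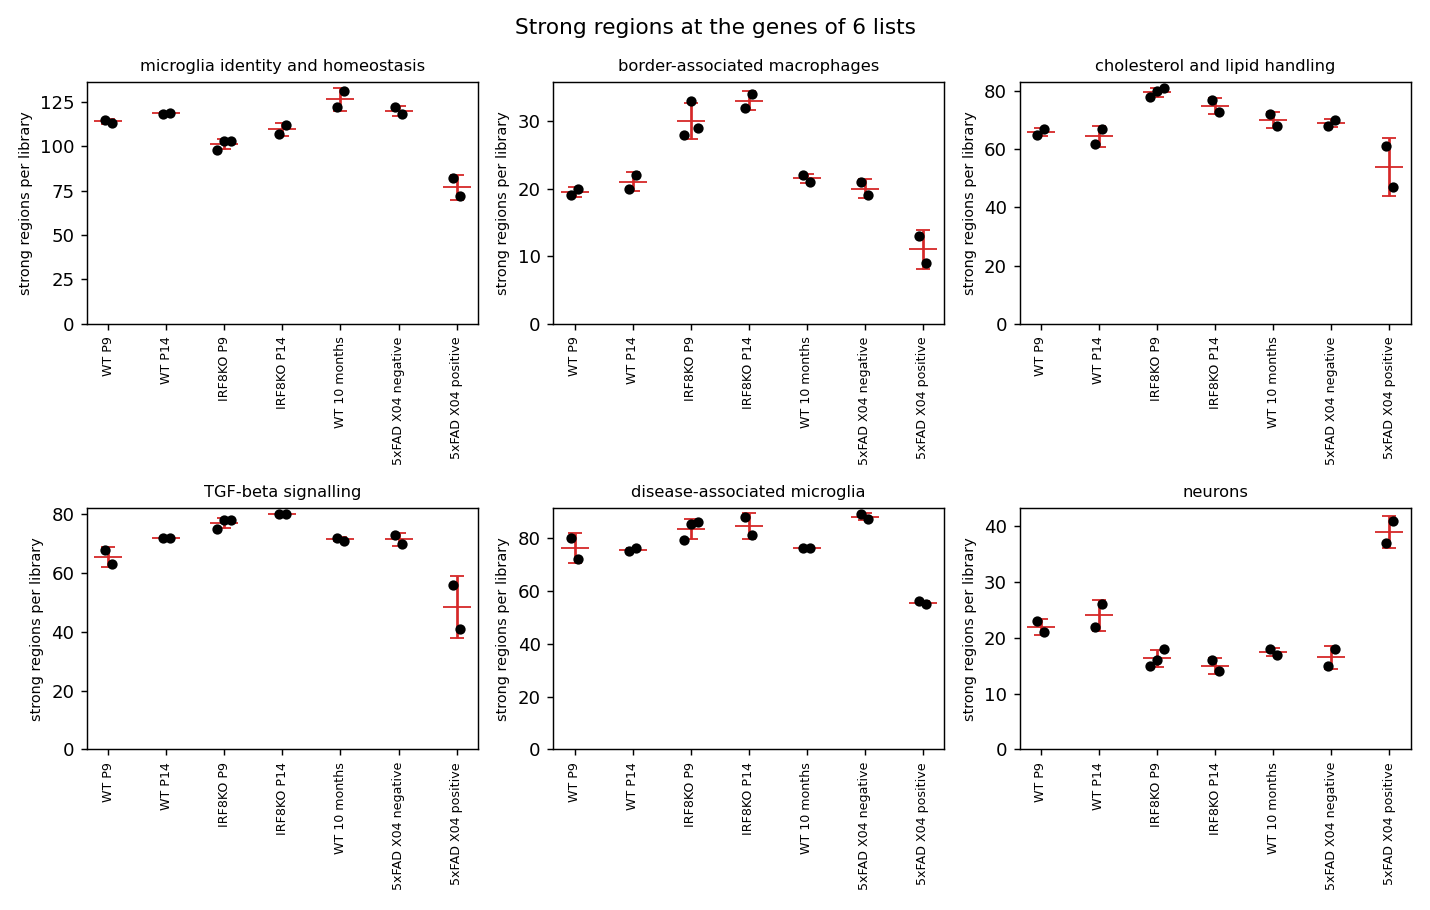
Strong regions per library (vertical axis, from 0) at the genes of 6 lists, by group (horizontal axis). Points are libraries, and red bars give the mean and SD. Border-associated macrophage genes have 30.0 ± 2.65 in IRF8KO and 19.5 ± 0.71 in WT at P9, and neuron genes have 39.0 ± 2.83 in X04 positive microglia.

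**Figure D3:**
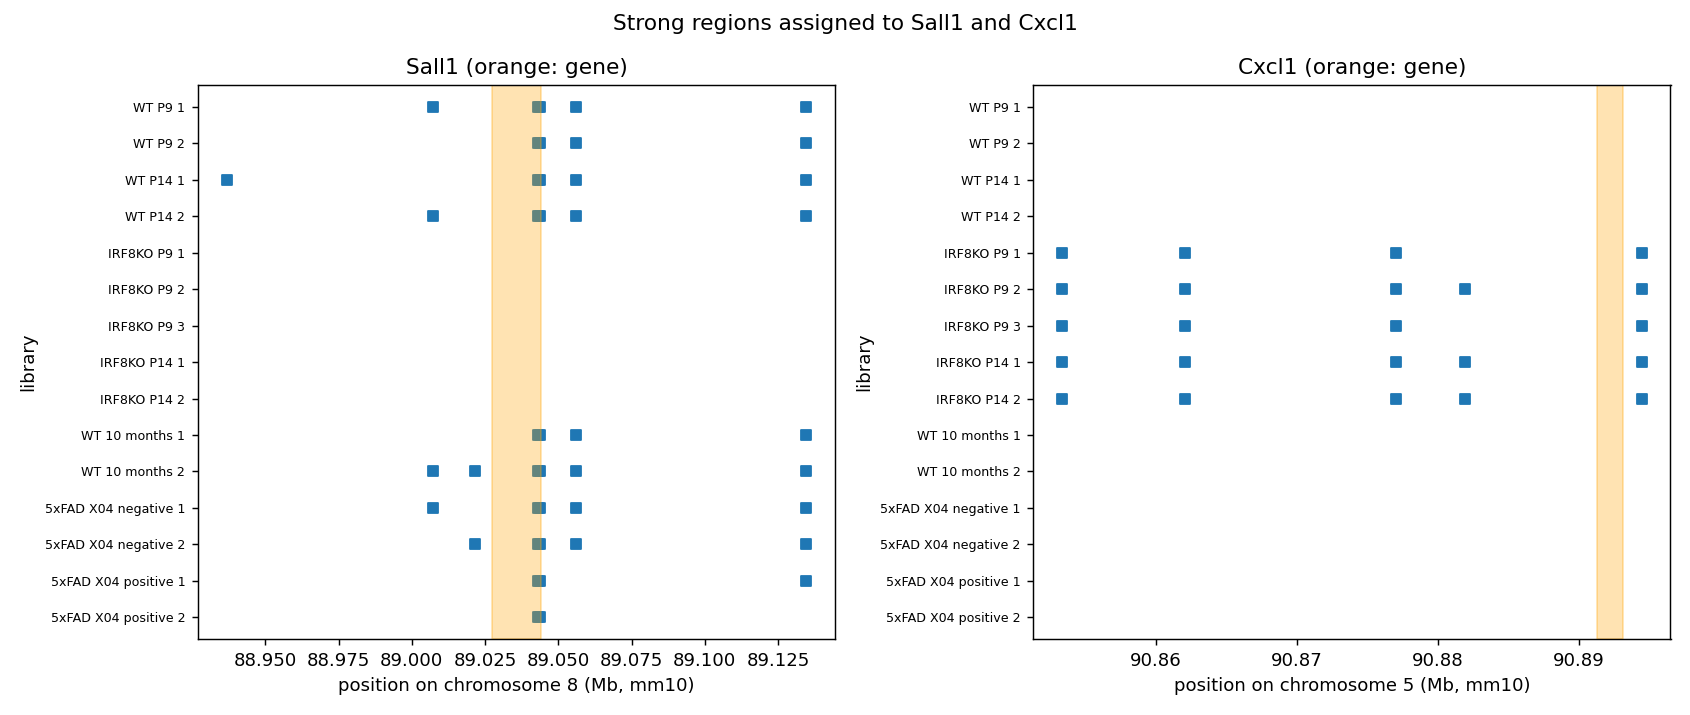
Strong regions assigned to Sall1 and Cxcl1 (squares) by library (vertical axis) along the chromosome (horizontal axis, Mb, mm10), with the gene in orange. Sall1 has 0.0 ± 0.0 in IRF8KO at P9 and P14, and Cxcl1 has 0.0 ± 0.0 in WT at both ages.

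Few regions, among them ones at Enox1, Rbpms, Hspa1a and Gucy1b1, differed between P9 and P14 by the rule of strong against absent. In WT, 1 region was higher at P14, with no gene within 100 kb, and 3 were lower, inside Enox1 and Rbpms and at a site with no gene within 100 kb. In IRF8KO, 2 were higher, inside Hspa1a, a heat shock gene, and 28 bp from Gucy1b1, and 0 were lower. The other splits of the same libraries gave up to 1 region in WT and 2 in IRF8KO. With strong against not strong, which also counts weaker regions, there were 620 higher and 622 lower in WT, where other splits gave up to 497. In IRF8KO there were 799 and 967, where other splits gave up to 390. Sample numbers 4 and 5 occur in IRF8KO at both ages, so these groups probably came from different sequencing runs. The strength of the IRF8KO libraries, as described above, was 77.47 ± 3.7 at P9 and 24.69 ± 2.63 at P14. Age can therefore not be told apart from run or library strength in the IRF8KO counts. For WT the labels give no run either. No list passed a test of whether the genotype difference changed with age (lowest adjusted p of the exact interaction test 0.35). That test permuted age labels within each genotype, so it is exact only if age has no effect in either genotype. These libraries allow few arrangements, so a lone list at the smallest possible p could not pass after adjustment over lists. The test therefore does not show that the genotype difference was the same at both ages. Before adjustment the lowest p of the exact interaction test was 0.05. Myeloid transcription factors and endothelial and mural genes had this p, and their genotype differences changed by 11.17 and −3.17 from P9 to P14. In IRF8KO, 8 regions were higher and 3 lower without replicate 1 of P14, and in WT 3 were higher without replicate 1 of P9 or of P14 and 6 lower without replicate 2 of P9.

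At 10 months 37 regions were higher and 16 lower in X04 negative 5xFAD microglia than in WT by the rule of strong against absent, which does not count weaker regions. With strong against not strong there were 1067 and 951, where other splits gave up to 539, and with 50000 top peaks the rule gave 194 and 94. Thy1, whose regulatory sequence drives the 5xFAD transgenes, held 6 of the higher regions and had strong regions in all 4 libraries of 5xFAD mice and in 0 of the other 11. The leading region of Thy1 lay 0.3 kb from the gene (chromosome 9, 44048721 to 44049121) with a mean rank of 6723.5 ± 3605.5 and an authors' fold of only 3.55 ± 0.09 (n = 2). Other higher regions lay inside Usp46, Acacb, Clec2g, Adgrg5, Pdgfrb, a marker of mural cells, and Albfm1, and near Frmd4a, Lrrc8c and Gm6749. Lower regions lay inside Zfp951, Klrd1, Klrb1f, Clec1b, Etv6, Gcn1, Efcab12 and Med13l and near Atp2b1 and Antxr2.

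Chromosome 5 held 14 of these calls, where 3.2 would be expected from the eligible regions, and chromosome 6 held 11, where 3.0 would be expected. No list passed against random lists. Genes of disease-associated microglia had 88.0 ± 1.41 strong regions in X04 negative microglia and 76.0 ± 0.0 in WT, and no region of that list was called. With 20000 top peaks this list had 51.0 ± 7.07 and 51.0 ± 1.41, and with 50000 it had 121.0 ± 2.83 and 113.5 ± 3.54. Astrocyte genes had 25.0 ± 0.0 strong regions in X04 negative microglia and 20 ± 0.0 in WT, and endothelial and mural genes had 16 ± 1.41 and 11.5 ± 0.71. The means were 15 and 13.5 for astrocyte and 7.0 and 6.5 for endothelial and mural genes with 20000 top peaks, and 33.0 and 30.0, and 30.0 and 26, with 50000. Without WT replicate 2 the counts were 83 higher and 26 lower, and without X04 negative replicate 1 they were 70 and 31.

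**Figure D4:**
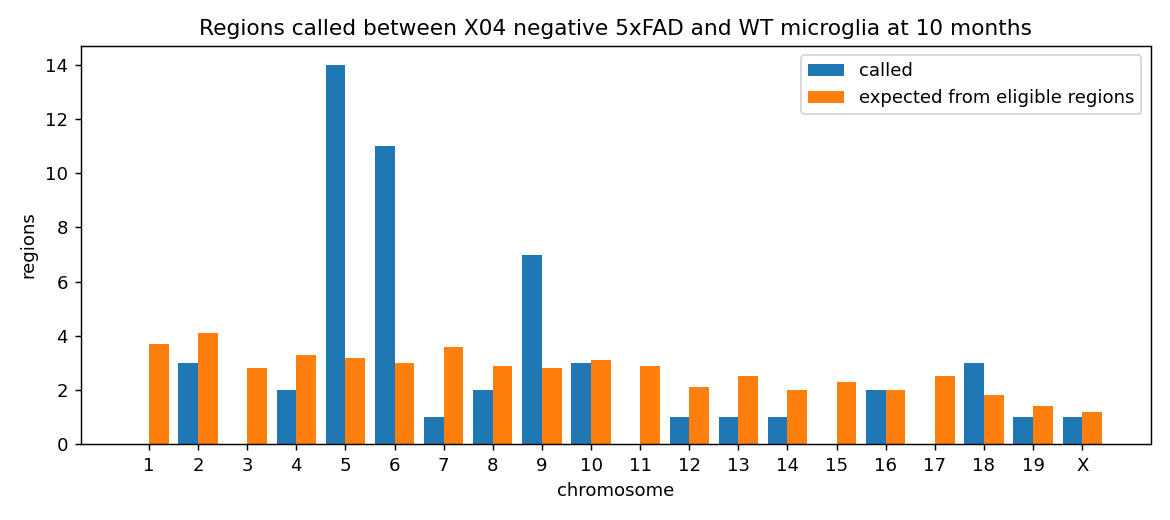
Regions called between X04 negative 5xFAD and WT microglia at 10 months (vertical axis, from 0) by chromosome (horizontal axis), beside the number expected from the eligible regions. Chromosomes 5 and 6 hold 14 and 11, where 3.2 and 3.0 are expected.

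Between X04 positive and X04 negative microglia 2298 regions were lower and 214 higher in X04 positive, and this excess of lower regions was not found without either X04 positive library (6814 higher and 5571 lower without replicate 1, and 4132 and 4139 without replicate 2). Bin1, an endocytosis gene in the microglial identity list, had 4 of the lower regions, and Bach2, Mef2c, Smad7 and Runx1, transcription factors and a TGF-beta inhibitor, had 3 each. Cebpb, Cebpa, Nfkbiz, Nfkb1, Elf1, Entpd1, Klf6, Treml4 and Irf8 had 2 each and Fosb 1. The leading lower regions lay at Ripk2, Clec2f, Acsl1, Serp1, Fam181b, Iffo1, Grm5, Adgre4, Wdr20 and Kif16b. Against WT, 2237 regions were lower and 183 higher, with Bin1 (5), Bach2 (4) and Mertk, a phagocytic receptor (3), among the lower. The X04 positive libraries were the weakest of the series, and the called regions of no list passed against random lists in either comparison.

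Neuron genes had 39.0 ± 2.83 strong regions in X04 positive, 16.5 ± 2.12 in X04 negative and 17.5 ± 0.71 in WT microglia, and lymphocyte genes had 20.5 ± 0.71, 9.5 ± 0.71 and 9.0 ± 1.41 (each n = 2). Microglial identity genes had 77.0 ± 7.07, 120.0 ± 2.83 and 126.5 ± 6.36, and disease-associated genes 55.5 ± 0.71, 88.0 ± 1.41 and 76.0 ± 0.0. With 20000 top peaks, X04 positive and X04 negative microglia had 21.5 ± 4.95 and 11.5 ± 2.12 strong regions at neuron genes, 10.0 ± 4.24 and 6.5 ± 2.12 at lymphocyte genes, 60.5 ± 9.19 and 87.0 ± 0.0 at identity genes, and 30.5 ± 2.12 and 51.0 ± 7.07 at disease-associated genes. With 50000 they had 44.5 ± 2.12 and 29.0 ± 1.41, 23.0 ± 2.83 and 16 ± 1.41, 90 ± 11.31 and 153.0 ± 11.31, and 70.5 ± 4.95 and 121.0 ± 2.83 in the same order. The called higher regions included Grin2b and Snap25, both neuronal, and Olfml3. The leading higher regions lay at Zfp949, Auts2, Sulf1, Plxdc2, Izumo1, Lipc, Sepsecs, Fam227b, Vstm4 and Prkdc, and their strength differed widely between the replicates, with an authors' fold of 34.54 ± 19.51 at Zfp949. Against WT there were 6545 higher and 5337 lower regions without X04 positive replicate 1, and 4025 and 3997 without replicate 2.

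In WT microglia at 10 months compared with P14, Mef2c, a transcription factor of microglial identity, had a higher region and Cdk1, a cell cycle kinase, a lower one, among 51 higher and 91 lower regions. The WT mice at 10 months received methoxy-X04 and those at P14 did not, so age and treatment cannot be told apart. The higher regions included one 78.1 kb from Mef2c and leading ones at Skint3, Map7, Rbpms, Dnajc15, Enox1, Gucy1b1, Gm51582, Clec1b, Etv6 and Mfhas1. The lower regions included ones inside Cdk1 and 81.5 kb from Pdgfra and 76.2 kb from Tgfb2, with leading ones at Dlgap1, Tbc1d9, Nudc, Frmd4a, Lrrc8c, Clec2g, Bri3bp, Ints10, Dok2 and Adgrg5. Of these regions, the ones at Clec1b, Etv6, Frmd4a, Lrrc8c, Clec2g, Bri3bp and Adgrg5 were also called between X04 negative 5xFAD and WT, as were 20 of the 47 regions of that comparison outside Thy1 in all, and both comparisons use the same 2 WT libraries at 10 months. Without WT replicate 2 at 10 months the counts were 142 and 270, with 50000 top peaks they were 333 and 773, and with strong against not strong 2178 and 2549.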

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

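No test in this part was chosen after a result was seen. Lck, a kinase of T lymphocytes, was the only one of 455 named or listed genes whose IRF8KO and WT libraries parted completely in opposite directions at the 2 ages, and none of the 21 lists did so. The difference between the genotype effects was −2.0 strong regions: the mean of IRF8KO minus WT was 1.0 at P9 and −1.0 at P14, and each library had 0 or 1. The difference was not tested.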

How the results depend on the processing

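Regions taken without the X04 positive libraries and the pairing by replicate number were chosen as alternatives after the values were seen, and the other alternatives were planned. Of 336 values under an alternative, 222 kept their direction and their side of the threshold or stayed within 1.5 times, 91 moved, 9 passed a threshold only there, 10 lost it and 4 reversed. The 222 include the list differences with a library left out, which were judged by direction alone. No test was run on those, so they do not show that a list stayed past the threshold. Regions taken without the X04 positive libraries moved no count by 1.5 times, with 2500 regions rising and 2478 falling in IRF8KO by the exact test over both ages. That test gave 1676 and 1705 with 20000 top peaks, and 3641 and 3659 with 50000. The motif comparison and its alternative were not run. With the replicate number as a block, which makes 4 pairs over both ages, microglial identity genes differed by −11.25, and the 8 lists past the test kept their direction in every pair. Each of these lost its call, since the smallest two-sided exact p of 4 pairs is 0.125. The deviations of libraries with the same number correlated at −0.035 to 0.013 across regions, so they share only a number. Regions called by strong against absent hold in every pair by construction. The pairs leave out IRF8KO replicate 3 at P9, and without it 579 regions were higher and 602 lower at P9. The weak X04 positive libraries limit what can be called absent there.

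In each pair of counts that follows, the former is of higher regions and the latter of lower ones. With 20000 top peaks, IRF8KO against WT gave 214 and 278 at P9, 292 and 334 at P14, and 131 and 198 at both ages. The same setting gave 91 and 714 for X04 positive against X04 negative, 76 and 664 against WT, 15 and 7 for X04 negative against WT, and 22 and 37 for 10 months against P14. For P14 against P9 it gave 1 lower region in WT and 0 higher in IRF8KO. With 50000 top peaks the genotype counts were 1544 and 1323 at P9, 1588 and 1890 at P14, and 858 and 957 at both ages. The age counts were then 4 and 9 in WT and 20 and 10 in IRF8KO, and those of 10 months against P14 were 333 and 773. X04 positive microglia gave 699 and 7479 against X04 negative and 627 and 7249 against WT, and X04 negative against WT gave 194 and 94. More top peaks make more regions strong by construction.

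With strong against not strong, which by construction also calls regions that were only weaker, the genotype counts were 4059 and 3860 at P9, 4164 and 4198 at P14, and 2494 and 2473 at both ages. Under that rule the age counts were 620 and 622 in WT, 799 and 967 in IRF8KO, and 2178 and 2549 for 10 months against P14. X04 positive microglia gave 1840 and 6651 against X04 negative and 1713 and 6401 against WT, and X04 negative against WT gave 1067 and 951. Absence judged in the full lists left 1 region higher at P14 in IRF8KO, and peak intervals gave 5 regions lower at P14 in WT and 9 in IRF8KO. With assignment within 20 kb, 0 gene lists passed in place of 1, with fewer regions per gene. The IRF family difference reversed to 0.67 with 20000 and 1.58 with 50000 top peaks, and with 50000 the inflammatory difference reversed to −5.75 and that of complement and phagocytosis to 5.92. The cause of these reversals was not tested.

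Leaving out each library in turn asks for fewer libraries and so can only add regions. The higher and lower regions then ran from 575 to 735 and 602 to 729 at P9, 721 to 822 and 826 to 948 at P14, and 314 to 347 and 418 to 440 at both ages. Complete separation at both ages, with no test, gave 2579 to 2847 and 2548 to 2811. The age counts ran from 1 to 3 and 3 to 6 in WT, 2 to 8 and 0 to 3 in IRF8KO, and 62 to 142 and 150 to 270 for 10 months against P14. X04 negative against WT gave 51 to 83 and 22 to 31. X04 positive microglia gave 348 to 6814 and 3407 to 5571 against X04 negative, and 324 to 6545 and 3318 to 5337 against WT, highest without X04 positive replicate 1. Without X04 positive replicate 2 these counts were 4132 and 4139 against X04 negative and 4025 and 3997 against WT. Without X04 negative replicate 1 they were 469 and 3561, without X04 negative replicate 2 348 higher, without WT replicate 1 324 and 3461, and without WT replicate 2 370 higher. X04 negative against WT gave 70 and 31 without X04 negative replicate 1, 59 higher without its replicate 2, 31 lower without WT replicate 1, and 83 and 26 without WT replicate 2. For 10 months against P14, omission of replicate 1 at 10 months gave 88 and 154, of replicate 2 142 and 270, and of P14 replicates 1 and 2 150 and 160 lower. For P14 against P9 in WT, 3 were higher without P9 or P14 replicate 1, and 2 higher and 6 lower without P9 replicate 2. In IRF8KO, 8 and 3 were found without P14 replicate 1, 4 higher without P14 replicate 2 or P9 replicate 2, and 1 lower without P9 replicate 3.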

Other observations

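The tests of chance splits, signal strength, a run difference at P9, border-associated macrophages, Thy1, chromosome segments and the odd group at 10 months were chosen after the result was seen, as were the choice of the neuron and lymphocyte lists for the length test and the matching on X04 negative regions. Of the 402 regions lower in IRF8KO at both ages, 72.6% were strong in both WT libraries and 80.6% in both X04 negative libraries at 10 months, against 13.9% in both X04 positive libraries. Of the 304 higher regions, 82.2%, 81.6% and 83.6% were absent from both libraries of these groups. The higher regions had been chosen as absent from WT at P9 and P14, which favours absence from WT at 10 months too. Of 26284 regions strong in both X04 positive or both WT libraries at 10 months, only 11776 were strong in all of them. The low share of lower regions in X04 positive microglia may therefore come from the weak signal of those libraries. Within 10 Mb of Irf8 lay 0 of the higher regions, where 3.5 were expected, and 6 of the lower ones, where 4.9 were expected. Immediate early genes had 83.0 ± 0.0 strong regions in WT at 10 months and 69.5 ± 3.54 at P14 (each n = 2), against 55.5 ± 0.71 and 48.0 ± 0.0 with 20000 top peaks and 105.0 ± 1.41 and 103.5 ± 0.71 with 50000. In X04 positive microglia 4 of 21 lists lost more strong regions than random lists did (permutation, adjusted p = 0.025 for each). The differences from X04 negative microglia were −12.5 for interferon response, −24.5 for the IRF family, −17.5 for antigen presentation and −13.5 for monocyte genes, where random lists gave means of −3.59, −12.45, −7.3 and −4.06. The random lists were matched on gene length and on the number of strong regions in X04 negative microglia. They were not matched on the strength of those regions, so the weak signal of the X04 positive libraries stays open as a source.

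IRF8KO microglia had 304 higher and 402 lower regions at both ages, and among 100 splits of the 9 libraries 1, the real one, gave as many in each direction, with 1 region the highest of the others. Every other split put libraries of a genotype on both sides, where a call needs a region strong in some and absent in others. The low counts show only that libraries of a genotype resembled each other, and do not say why. Signal strength as the whole cause is argued against, since it was stronger in IRF8KO at P9 and in WT at P14 and yet there were 0 opposite calls by strong against absent, and 0.7 per 100 calls in the same direction by strong against not strong. A minority of other cells in the IRF8KO sorts cannot account for all of the lower regions, because 60 regions in the top 10000 of all 4 WT libraries had no summit among the 126070 top peaks of any of the 5 IRF8KO libraries, and 48 had none in their full lists. Border-associated macrophages in the IRF8KO sorts stay open as a source of gained regions, since 8 of their 14 measured genes had a higher mean number of strong regions at both ages, 1 had a lower one, and Lyve1 and Cbr2 had 1.0 ± 0.0 and 2.0 ± 0.0 in both genotypes, which decides nothing in a list noticed for its gain; a first bound of over 7 genes, which was met, was raised to 12 for that reason. A difference between sequencing runs at P9 alone is argued against as the whole cause of the calls at P9, since regions called the same way at P14 were 40.6 times those expected of independent lists for lower and 54.3 times for higher regions, while a run difference shared by both ages, a change of state in the microglia, and replacement of most cells by another type stay open.

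Thy1 regions were strong in all 4 libraries of 5xFAD mice and in 0 of the other 11, and the 6 called regions lay at most 1.1 kb from the gene, which may reflect copies of the 5xFAD transgenes, which carry Thy1 sequence. The test as first run took all 10 strong regions and failed its bound of 10 kb, because 1 lay 37.9 kb away; it was then limited to called regions. Of the 47 other regions called between X04 negative 5xFAD and WT, 29 had another within 10 Mb, where random sets of eligible regions gave a mean of 15.2 (p = 0.0006 by permutation), so chromosome segments of another strain are a candidate explanation. That the odd group is the 10 month WT stays open, since in both WT libraries at P14 20 of the regions (42.6%, where over 50% was asked) had the state of X04 negative 5xFAD, 4 had that of WT at 10 months and 23 had neither and decide nothing. The bound against it was first 50% or fewer of all 47, and was changed because it counted undecided regions against it, and an effect of the disease on these regions stays open too.

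The regions lower in X04 positive microglia may come from the weak signal of the X04 positive libraries, since 1 of those lost lay among the strongest of 5 equal classes of X04 negative regions and 1151 among the weakest, a ratio of 0.001. The share lost ran from 0.02% in the strongest class to 23.92% in the weakest, against 0.76% to 3.66% for regions lower in IRF8KO at P9. Neuron genes had 22.5 more strong regions in X04 positive than in X04 negative microglia, where random lists of the same gene lengths gave a mean of 0.8 (p = 0.003 by permutation), and for lymphocyte genes the gain was 11 (p = 0.054). Random lists also matched on strong regions in X04 negative microglia gave a mean of 8.63 for neuron genes (permutation p = 0.017, adjusted p = 0.071 over 21 lists) and of 6.87 for lymphocyte genes (permutation p = 0.29), so scattered peaks of a weak library stay open. The bound written before the length test, p under 0.05 for neuron genes, was met and went against scattered peaks. The further match was added afterwards, because the list was picked for its gain and genes closed in microglia can only gain. Neuronal material in or attached to plaque-bearing cells, and a change in the X04 positive microglia themselves, stay open and were not tested.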
